A study of Homo sapiens with 6 samples.

How the data were processed

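RNA sequencing was done on 6 samples of SUM-1315, an established triple-negative breast cancer cell line, in 3 groups of 2 samples. The groups received lentivirus with a short hairpin RNA (shRNA) against green fluorescent protein (shGFP, the control) or with 1 of 2 hairpins against IMP3 (shIMP3-75 and shIMP3-77). IMP3 here is the RNA-binding protein encoded by IGF2BP3. The gene whose official symbol is IMP3 is a different one. Per the labels' protocols, cells at passage 12 to 15 were infected for 3 days and selected for 2 to 4 days in puromycin at 2 µg/mL. No label says whether the 2 samples of a group came from separate cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical. P-values of gene lists do not measure the spread between separate cultures either.

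Per the submitters' processing notes, TopHat2 2.0.9, Bowtie2 2.1.0, Cufflinks 2.2.1 and Cuffdiff were used with the genome build hg19. The version of Cuffdiff and the gene annotation are not given in the sources used here. Per the file headers, the authors deposited 1 table per hairpin, each with the FPKM (fragments per length of transcript and per total of mapped fragments) of the 2 hairpin libraries and of the 2 shGFP libraries, and the group means of FPKM. The same deposited tables give a log2 fold change, a test statistic (a score with no fixed range), a p-value, a q-value and a status per record. The deposited log2 fold change is control over hairpin. Every fold change and test statistic given here has its sign turned, so that a positive value means higher with the hairpin. Loci are in hg19, with the start moved by 1 so that positions count from 1.

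Each table was scaled separately by the authors. The shGFP columns of the shIMP3-75 table were 0.946 (replicate 1) and 0.942 (replicate 2) times those of the shIMP3-77 table. All tests were made within a table. By a rule fixed before the data were examined, the hairpins were to be tested against each other only in 1 normalization or with identical shGFP columns, so that test was not run, although the constant factors would allow a common scale. A record is a symbol at a locus. Some symbols have several records at 1 locus, and what separates them is not stated. Some records join several genes. For these genes reads may be shared. Where a named symbol had several records, the one with the highest mean FPKM was taken.

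The tables held the authors' comparisons and FPKM per library. As fixed before the data were examined, the authors' q at a threshold of 0.05 was the main test for single genes, over records with a usable test (status OK). A gene is called if it passes. Counts of reads were not analysed here, so a test on counts was not run. As a second test, limma was run within each table on log2(FPKM + 1), with Benjamini-Hochberg adjustment over the records with a usable test. Log2 differences from limma are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. On simulated data with the spread of the real records, limma recovered 69 of 100 records changed 2-fold and 98 of 100 changed 4-fold over the 14228 records of the shIMP3-75 table. Over the 14310 records of the shIMP3-77 table it recovered 62 of 100 and 98 of 100. False calls among the unchanged records numbered 12 (shIMP3-75 table) and 13 (shIMP3-77 table). With no record changed they numbered 0 and 3.

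Gene lists, 31 in number and holding 791 genes, were fixed before the data were examined. Each was tested in each comparison with camera of limma (preset correlation 0.01) on the limma fit, and again with a correlation estimated from 2 residual degrees of freedom, adjusted by Benjamini-Hochberg over the 60 tests of lists with at least 3 usable members. Beside it stand the called members by the authors' q, the counts from the authors' p adjusted over the list alone, and the percentile of the list's median log2 difference among 10000 random lists matched on expression. With a preset correlation, the camera p-value sets a list's shift against the spread across genes, not between samples. All list genes were matched to a record by symbol, by an older symbol or within a joined record.

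The overlap of calls and the agreement of fold changes between the comparisons were set beside 100 simulations of unchanged groups that share the 2 shGFP libraries, with each record's spread taken from limma, and beside the overlap of independent lists. The shGFP libraries cannot be split with 2 in each part.

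Named genes were chosen by a rule fixed before the data were examined. It holds 14 genes tied to the target or to this cell type. It adds the 10 most raised and 10 most lowered genes called in both comparisons in 1 direction, ranked by the smaller fold change. From each comparison it takes the 5 most raised and 5 most lowered genes. From each list it takes up to 4 members, those called in both comparisons first. It ends with up to 5 genes called in both in opposite directions. Ranked genes outside the lists needed at least 1 FPKM in both groups, except those called in opposite directions, and symbols of unnamed loci, small RNAs and joined records were passed over.

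Alternatives covered the q threshold, a fold minimum, a minimum of 1 FPKM, median-centring, the set of records behind the q, the pseudocount, leaving out each library, and the replicate number as a block. For named genes the mean FPKM of the hairpin libraries was also set over each shGFP library alone, as a log2 ratio with no test. Absolute depth is not known from FPKM. In records with few reads, the ratio of 2 libraries' values recurs at 1 value, which gives relative depth on the authors' scale. Within 0.2% tolerance, 350 to 407 records shared the most common ratio. Relative to shGFP replicate 1, this gave a depth of 0.857 and 0.753 for the shIMP3-75 libraries, 0.920 and 0.817 for the shIMP3-77 libraries, and 0.993 for shGFP replicate 2 in the shIMP3-75 table. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.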

Results

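Messenger RNA levels were measured by RNA sequencing in SUM-1315 cells, an established line of triple-negative breast cancer, after lentiviral delivery of a control hairpin (shGFP) or of 1 of 2 hairpins against IMP3 (shIMP3-75 and shIMP3-77), with 2 samples in each group. IMP3, encoded by IGF2BP3, is an RNA-binding protein of the insulin-like growth factor 2 mRNA-binding family. The 2 deposited tables held 24499 and 24500 records, of which 14228 (shIMP3-75) and 14310 (shIMP3-77) had a usable test. FPKM per library summed to 682819 and 639331 for shIMP3-75, against 506020 and 578504 for shGFP in the same table. In the other table it summed to 558333 and 568198 for shIMP3-77, against 534642 and 614113 for shGFP. The shGFP libraries lay further apart than the hairpin libraries. The SD of the log2 difference between replicates over records was 0.52 for shGFP against 0.41 for shIMP3-75, and 0.53 against 0.40 for shIMP3-77.

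The first question was whether the target was lowered. IGF2BP3 (hg19, chromosome 7, 23338940 to 23510306) was at 21.3 ± 2.8 FPKM (SD, n = 2) with shIMP3-75 against 43.7 ± 6.5 (SD, n = 2) with shGFP. With shIMP3-77 it was at 15.3 ± 0.84 FPKM (SD, n = 2) against 46.2 ± 6.7 (SD, n = 2). In the authors' deposited table its log2 fold change was -1.03 (q = 0.00221) and -1.60 (q = 0.00266), so it fell with both hairpins. By limma the adjusted p was 0.0414 and 0.0363, with log2 differences of -0.999 (SE 0.178) and -1.53 (SE 0.165). It lost the threshold when a hairpin library was left out. The log2 difference was then -1.13 and -0.87 without shIMP3-75 replicate 1 or 2 (SE 0.280, adjusted p = 0.297 and 0.326). It was -1.48 and -1.58 without shIMP3-77 replicate 1 or 2 (SE 0.287, adjusted p = 0.272 and 0.226). The spread then came from the 2 shGFP libraries alone, and the SE grew. The related gene IGF2BP2 did not pass in either comparison, with log2 fold changes of 0.51 (q = 0.309) and 0.29 (q = 0.644) in the authors' deposited table. IGF2BP1 was at 0.444 FPKM with shIMP3-75 against 0.435 with shGFP, and at 0.50 with shIMP3-77 against 0.461 in the other table. The joined record that holds the unrelated gene IMP3 had log2 fold changes of 0.53 (q = 0.279) and -0.03 (q = 0.971) in the authors' deposited table.

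**Figure D1:**
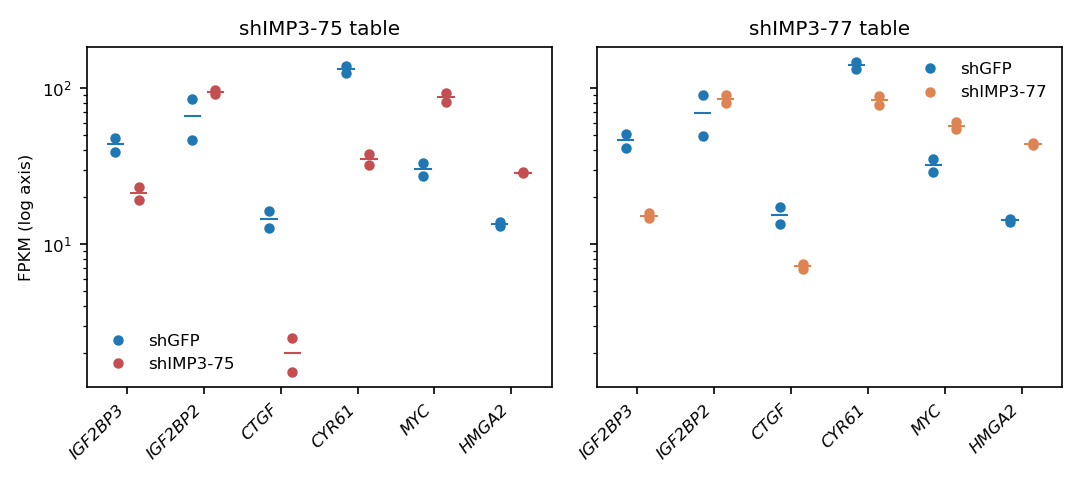
FPKM on a log axis for 6 genes in the shIMP3-75 table (left) and the shIMP3-77 table (right), with 1 point per library and a bar at the mean of 2 libraries. IGF2BP3 lies at 21.3 FPKM with shIMP3-75 and 15.3 FPKM with shIMP3-77, below shGFP in both tables, while MYC and HMGA2 lie above shGFP in both.

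The second question was what changed with shIMP3-75. CTGF and CYR61, which respond to the mechanosensitive coactivators YAP and TAZ, fell. CTGF was at 2.01 ± 0.69 FPKM (SD, n = 2) against 14.5 ± 2.6 (SD, n = 2) with shGFP, and CYR61 at 35.0 ± 4.0 against 132 ± 8.9 (SD, n = 2). IL6, a cytokine, was at 0.545 ± 0.13 FPKM (SD, n = 2) against 7.73 ± 1.2 (SD, n = 2), and COL5A2, a fibrillar collagen, at 19.4 ± 0.058 against 72.0 ± 7.9 (SD, n = 2). MYC rose from 30.4 ± 4.2 to 87.4 ± 8.4 FPKM (SD, n = 2), and MCM5, a subunit of the replicative helicase, from 16.4 ± 0.59 to 35.4 ± 1.3 (SD, n = 2). ATP5G1, a subunit of the mitochondrial ATP synthase, had the largest rise among called genes that passed the naming rule for this comparison, from 9.37 ± 0.23 to 79.1 ± 8.4 FPKM (SD, n = 2).

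Of 14228 records, 1414 were called with shIMP3-75, 613 higher and 801 lower, by the q of the authors' deposited table. The median log2 fold change of records with at least 1 FPKM in both groups was 0.11, and centring on it gave 395 higher and 1015 lower, so that the share of higher calls moved from 43.4% to 28.0%. By limma 1240 records were called, 687 higher and 553 lower, of which 843 were also called by the authors' test. That count rested on the libraries used: limma called 21 records without either shIMP3-75 library, 4640 without shGFP replicate 1 and 3460 without shGFP replicate 2.

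Among the YAP/TAZ-TEAD target genes, 8 of 21 measured members fell and 0 rose, 8 adjusted over the list alone. Log2 fold changes in the authors' deposited table were -2.85 for CTGF, -1.92 for CYR61, -2.66 for IGFBP3 and -1.85 for CCDC80. Against shGFP replicate 1 alone the log2 ratio of CCDC80 was -1.22. The list fell (camera of limma, adjusted p = 2.78e-05; adjusted p = 0.678 with an estimated correlation), and its median lay at percentile 0.03 of random lists. Of 21 components of the Hippo pathway, which restrains YAP and TAZ, 4 fell and 0 rose, 7 adjusted over the list alone (adjusted p = 0.0113; adjusted p = 0.678 with an estimated correlation). AMOTL2 fell with a log2 fold change of -1.75, FRMD6 of -1.73, MOB1A of -1.25 and YAP1 of -0.72 in the authors' deposited table. WWTR1, which encodes TAZ, was at 0.13 (q = 0.910) in the authors' deposited table.

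Of 27 collagen and basement membrane genes 9 fell and 1 rose with shIMP3-75, of 21 matrix proteases and inhibitors 4 fell and 0 rose, and of 13 integrins 5 fell and 1 rose. Adjusted over the list alone, 11 fell and 2 rose, 7 fell and 0 rose, and 6 fell and 2 rose. The lists fell with adjusted p = 0.000332, 0.000133 and 0.0294 by camera of limma (adjusted p = 0.721, 0.678 and 0.678 with an estimated correlation), and the integrin list was past the threshold only with shGFP replicate 1 (adjusted p = 0.104 without it). ITGB8 had a log2 fold change of -2.51, ADAMTS6 of -1.75, PLAT, the tissue plasminogen activator, of -1.62, and ITGA5 of 1.05 in the authors' deposited table. Against shGFP replicate 2 alone the log2 ratio of ITGB8 was -1.81. Of 19 mesenchymal genes 7 fell and 2 rose (8 fell and 2 rose adjusted over the list alone), with S100A4 at -1.32 and LOX at -1.25 in the authors' deposited table (camera of limma, adjusted p = 0.0294; adjusted p = 0.678 with an estimated correlation). SNAI2, a transcription factor of the mesenchymal state, fell by 1.08 on the log2 scale and CD44 by 0.87 in the authors' deposited table. Of 11 epithelial genes 3 fell and 0 rose, 3 adjusted over the list alone, with CDH3 at -1.82 and CDH1 at -2.25 in the authors' deposited table (camera of limma, adjusted p = 0.0453; adjusted p = 0.752 with an estimated correlation; adjusted p = 0.265 without shGFP replicate 2, 0.0750 without shIMP3-75 replicate 1 and 0.0563 without shIMP3-75 replicate 2).

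Of 21 targets of NF-kB and cytokines 5 fell and 0 rose, 5 adjusted over the list alone (camera of limma, adjusted p = 0.00455; adjusted p = 0.678 with an estimated correlation). IL6 had a log2 fold change of -3.82, CXCL1 of -1.65, IER3 of -1.45 and PTGS2 of -1.44 in the authors' deposited table. Among 23 genes of RAS/MAPK output 4 fell and 1 rose, the same counts adjusted over the list alone, with DUSP6 at -1.42 and EGR1 at -1.04 in the authors' deposited table. That list passed with adjusted p = 0.0195 by camera of limma (adjusted p = 0.678 with an estimated correlation), and with adjusted p = 0.214 without shGFP replicate 1 it did not.

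Of 76 cytosolic ribosomal protein genes 26 rose and 0 fell with shIMP3-75, 58 adjusted over the list alone, and the list's median lay at percentile 100 (camera of limma, adjusted p = 4.59e-15; adjusted p = 0.695 with an estimated correlation). RPS20 rose from 535 ± 16 to 1298 ± 40 FPKM (SD, n = 2) and RPL39 from 695 ± 124 to 1599 ± 77 (SD, n = 2). Of 51 nuclear-encoded genes of oxidative phosphorylation 8 rose and 0 fell, 10 adjusted over the list alone (camera of limma, adjusted p = 2.75e-06; adjusted p = 0.678 with an estimated correlation), with log2 fold changes of 3.08 for ATP5G1, 1.02 for COX5A and 0.86 for ATP5D in the authors' deposited table. Of 39 genes of DNA replication and S phase 10 rose and 0 fell, 12 adjusted over the list alone, with POLE2 at 1.29, MCM5 at 1.11 and CCNE1 at 1.11 in the authors' deposited table. The log2 ratio of POLE2 was 0.75 against shGFP replicate 1 alone and 2.15 against shGFP replicate 2 alone. The S-phase list rose with adjusted p = 0.00583 by camera of limma (adjusted p = 0.721 with an estimated correlation), and did not pass without shGFP replicate 2 (adjusted p = 0.0929). Of 35 genes of G2/M and mitosis 1 rose, AURKB (log2 fold change 1.37 in the authors' deposited table), and 2 fell (3 and 2 adjusted over the list alone), and the list was not past the threshold (adjusted p = 0.510). The endonuclease gene DICER1 rose with a log2 fold change of 1.86 in the authors' deposited table, alone among 12 genes of RNA interference (2 adjusted over the list alone). Their list was not past the threshold (camera of limma, adjusted p = 0.112). It passed, higher, without shGFP replicate 2, but not without shGFP replicate 1.

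The third question was what changed with shIMP3-77. HMGA2, a chromatin protein whose mRNA is reported to be bound by IGF2BP3, rose from 14.2 ± 0.50 to 43.9 ± 1.1 FPKM (SD, n = 2), and CAV2, a caveolin, from 9.06 ± 2.6 to 48.4 ± 1.3 (SD, n = 2). EGFR rose from 15.5 ± 1.8 to 30.5 ± 0.44 FPKM (SD, n = 2). TIMP2, an inhibitor of metalloproteinases, fell from 48.1 ± 8.0 to 8.86 ± 0.85 FPKM (SD, n = 2), and ASNS, asparagine synthetase, from 67.5 ± 18 to 15.1 ± 3.8 (SD, n = 2). CCND1, a G1 cyclin, fell from 26.5 ± 0.26 to 11.6 ± 1.8 FPKM (SD, n = 2).

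Of 14310 records, 1061 were called with shIMP3-77, 286 higher and 775 lower, by the q of the authors' deposited table. The median log2 fold change was -0.11, and centring on it gave 418 higher and 528 lower, so that the share of higher calls moved from 27.0% to 44.2%. By limma 340 records were called, 126 higher and 214 lower, of which 272 were also called by the authors' test. Limma called 17 and 14 records without shIMP3-77 replicate 1 or 2, 4776 without shGFP replicate 1 and 1961 without shGFP replicate 2.

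Of 16 heat shock genes 2 rose with shIMP3-77 and 0 fell, 6 adjusted over the list alone (camera of limma, adjusted p = 0.000718; adjusted p = 0.678 with an estimated correlation). HSPA8, a constitutive HSP70, had a log2 fold change of 1.00 and DNAJB1, its cochaperone, of 0.75 in the authors' deposited table. Of 21 TGF-beta and SMAD target genes 5 rose and 1 fell, 5 and 2 adjusted over the list alone, among them INHBA at 3.14 and CTGF at -1.09 in the authors' deposited table. This list rose with adjusted p = 0.0251 by camera of limma (adjusted p = 0.678 with an estimated correlation). Its 20 members usable in the other table held 6 that fell and 1 that rose with shIMP3-75 (adjusted p = 0.0513), 6 and 2 adjusted over the list alone. That list passed, lower, without shGFP replicate 2 or either shIMP3-75 replicate, but not without shGFP replicate 1. The YAP/TAZ-TEAD targets were not past the threshold with shIMP3-77 (adjusted p = 0.874), with 3 members higher and 2 lower, CTGF and CYR61, and 4 and 4 adjusted over the list alone. By camera of limma the lists of S phase (adjusted p = 0.829), oxidative phosphorylation (0.899), collagens (0.303) and proteases (0.280) were not past it either. Nor were the lists of integrins (adjusted p = 0.559), mesenchymal genes (0.604) and NF-kB (0.745) by camera of limma. The collagen list passed, higher, without shGFP replicate 2, but not without shGFP replicate 1. Markers of other cell types were few: of 5 fibroblast and stromal markers 2 fell with shIMP3-75 (adjusted p = 0.0513), and 1 rose and 1 fell with shIMP3-77 (adjusted p = 0.559), of 3 leukocyte markers 0 were called with shIMP3-75 and 1 rose with shIMP3-77, CD68 in a joined record (adjusted p = 0.764 and 0.228), and 1 endothelial marker was usable. The stromal list with shIMP3-75 passed, lower, without shGFP replicate 2 or shIMP3-75 replicate 1, but not without shGFP replicate 1. With the test statistic of the authors' deposited table in camera, the adjusted p with shIMP3-75 was 0.00514 for the stromal list and 0.0014 for the TGF-beta list. By camera of limma with an estimated correlation neither passed with shIMP3-75 (adjusted p = 0.721 and 0.678). Adjusted over the list alone, 4 stromal markers fell with shIMP3-75 and 2 rose and 2 fell with shIMP3-77, and 1 leukocyte marker rose with each hairpin. Whether any list differed between the hairpins was not tested.

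Both comparisons used the same 2 shGFP libraries, so a list that passed in both is not independent evidence. Interferon-stimulated genes fell: of 38 members 17 fell and 1 rose with shIMP3-75, and 12 fell and 0 rose with shIMP3-77, 11 of them lower in both. Adjusted over the list alone, 23 fell and 1 rose, and 22 fell and 0 rose. Log2 fold changes with shIMP3-75 and shIMP3-77 in the authors' deposited table were -3.67 and -3.35 for OAS1, -2.14 and -3.12 for BST2, -2.04 and -3.05 for IFITM1 and -2.75 and -2.83 for XAF1. The list fell with adjusted p = 1.68e-09 and 1.33e-06 by camera of limma (adjusted p = 0.721 and 0.721 with an estimated correlation). Among the shGFP libraries replicate 2 was higher, with a list median 0.38 (log2) above replicate 1 in the shIMP3-75 table. In that table OAS1 was at 0.936 and 4.50 FPKM in shGFP replicates 1 and 2 and at 0.301 and 0.127 with shIMP3-75. BST2 was at 16.9 and 58.3 FPKM against 7.01 and 10.1, and IFITM1 at 24.0 and 47.3 against 9.16 and 8.22. By limma OAS1 did not pass (adjusted p = 0.123 and 0.165), nor did BST2 (adjusted p = 0.108 and 0.0799). Against shGFP replicate 1 alone the log2 ratios were -2.13 and -1.81 for OAS1 and -0.98 and -1.96 for BST2.

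Genes of the unfolded protein and ATF4 response, which handle protein folding and amino acid stress, fell as well. Of 30 members 13 fell and 2 rose with shIMP3-75, and 14 fell and 0 rose with shIMP3-77, 11 of them lower in both. Adjusted over the list alone, 18 fell and 2 rose, and 15 fell and 1 rose. TRIB3 had log2 fold changes of -1.81 and -2.77, CHAC1 of -2.06 and -2.24, DDIT4 of -1.14 and -2.25 and ASNS of -0.71 and -2.16 in the authors' deposited table. The list fell with adjusted p = 9.74e-05 and 0.000243 by camera of limma (adjusted p = 0.721 and 0.721 with an estimated correlation). Its median in shGFP replicate 2 was 0.46 (log2) above replicate 1 in the shIMP3-75 table, and TRIB3 was at 4.70 and 15.0 FPKM in the 2 shGFP libraries against 3.19 and 2.43 with shIMP3-75. Against shGFP replicate 1 alone the log2 ratios of TRIB3 were -0.74 and -1.69. Cytosolic ribosomal protein genes rose as a list with shIMP3-77 too, with 2 members higher, RPS20 and RPS21, and 1 lower, RPL34, the same counts adjusted over the list alone (adjusted p = 1.69e-05; adjusted p = 0.721 with an estimated correlation). That call was not kept without shGFP replicate 1 (adjusted p = 0.103).

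**Figure D2:**
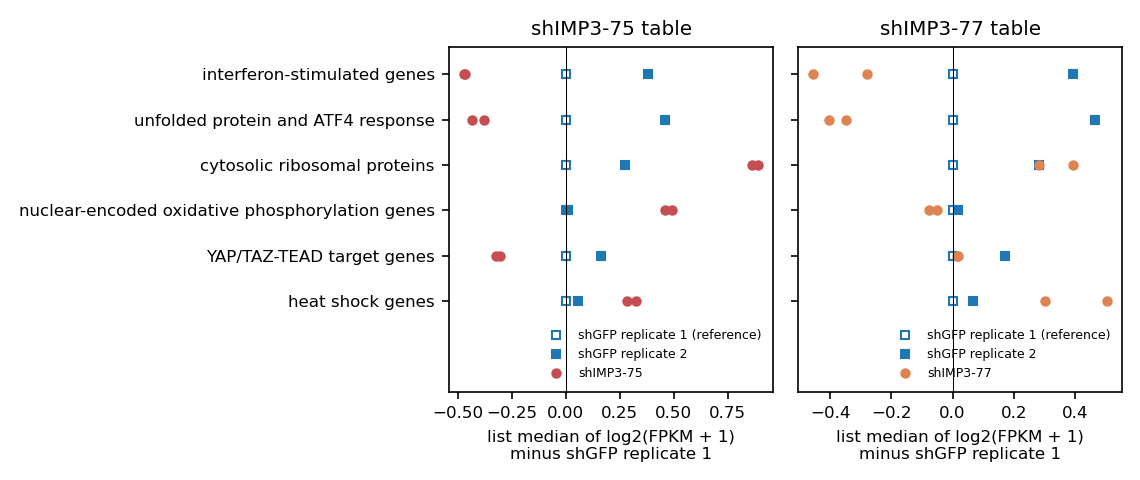
Median over the members of 6 gene lists of log2(FPKM + 1) minus shGFP replicate 1, for each library of the shIMP3-75 table (left) and the shIMP3-77 table (right). For interferon-stimulated genes and the ATF4 response, both hairpin libraries lie below shGFP replicate 1 in each table, and shGFP replicate 2 lies above it by 0.38 and 0.46 in the shIMP3-75 table.

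Genes with a known tie to the target or to this cell type were looked up in both comparisons. MYC rose, with log2 fold changes of 1.52 and 0.84, and HMGA2 with 1.10 and 1.62 in the authors' deposited table. CTGF, at -2.85 and -1.09, and CYR61, at -1.92 and -0.74, fell in the authors' deposited table. IGF2, in a joined record with INS, fell with -1.96 and -2.64 in the authors' deposited table, at 0.225 and 0.149 FPKM with the hairpins. By limma IGF2 did not pass, with log2 differences of -0.61 and -0.74 (adjusted p = 0.0680 and 0.0778). MYC, CTGF and CYR61 did not pass by limma with shIMP3-77 (adjusted p = 0.0675, 0.0559 and 0.0711), nor did SNAI2 and YAP1 with shIMP3-75 (adjusted p = 0.0680 and 0.0521). Over all genes named by the rule, limma called 63 of the 102 that the authors' test called with shIMP3-75, and 35 of 74 with shIMP3-77. WNT5B, a non-canonical Wnt ligand, had -1.59 (q = 0.0276) and -1.03 (q = 0.312), YAP1 had -0.72 (q = 0.0387) and -0.48 (q = 0.352), and SNAI2 had -1.08 (q = 0.00221) and 0.62 (q = 0.131) in the authors' deposited table. SOX2 had no usable test and lay below 1 FPKM. Of 10 reported IGF2BP3-bound transcripts 4 rose and 4 fell with shIMP3-75 and 2 rose and 3 fell with shIMP3-77, the same counts adjusted over the list alone, and the list was not past the threshold (adjusted p = 0.829 and 0.952).

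The largest shared rises, ranked by the smaller of the 2 fold changes, included ATP5G1 (3.08 and 2.44 in the authors' deposited table), ITPK1, an inositol phosphate kinase (2.43 and 2.59), ZNF367 (2.2 and 2.26), CYBRD1, a ferric reductase (1.95 and 2.07), and CAV2 (1.77 and 2.42). The metallothioneins MT1E (1.73 and 1.68) and MT1X (1.61 and 1.89) and the kinase MAPK6 (1.55 and 1.61) followed in the authors' deposited table. Beside XAF1, BST2, IFITM1, CHAC1 and TRIB3, the largest shared falls included JDP2 (-2.11 and -2.05), PLEKHA4 (-2.47 and -1.89), ERRFI1, a feedback inhibitor of EGFR (-2.01 and -1.85), and PSG9 (-1.73 and -2.27) in the authors' deposited table. ERRFI1 was at 56.3 ± 2.3 FPKM (SD, n = 2) with shIMP3-75 and 66.7 ± 3.0 (SD, n = 2) with shIMP3-77, against 227 ± 31 and 241 ± 34 (SD, n = 2) with shGFP in the respective tables, which were scaled separately. Several of these folds, with BST2 and TRIB3 among them, rested on shGFP libraries that lay far apart. In the shIMP3-75 table PLEKHA4 was at 17.7 and 65.3 FPKM in shGFP replicates 1 and 2, JDP2 at 5.15 and 20.2, and MT1X at 17.3 and 4.4. With replicate 1 alone as control, the log2 ratios were -1.24 and -0.66 for PLEKHA4, -0.81 and -0.74 for JDP2 and 0.93 and 1.22 for MT1X. By limma these genes, TRIB3 and BST2 did not pass in either comparison: adjusted p = 0.0873 and 0.194 for PLEKHA4, 0.141 and 0.188 for JDP2, 0.110 and 0.109 for MT1X, 0.138 and 0.0910 for TRIB3 and 0.108 and 0.0799 for BST2.

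Among 14105 records usable in both tables, 78 were called higher in both comparisons and 233 lower in both. Independent lists of these sizes would share 11.6 and 44.0, and unchanged groups against the same shGFP libraries shared 78.2 and 201 among as many top-ranked records (mean of 100 simulations). By limma 40 were higher and 62 lower in both. Part or all of the excess over independent lists may come from the shared controls, so it is not read as a shared effect. The controls were not split, as each part would hold 1 library. Across 12792 records the deposited log2 fold changes had a Pearson r of 0.455 and a Spearman rho of 0.419, against 0.50 and 0.473 in the simulations; records are not independent replicates. The covariance of limma log2 differences across 12815 records was 0.133 against 0.0277 simulated, and 60.7% had the same sign against 66.6% simulated. The simulation gave all libraries of a record 1 spread, which sets its correlation and same-sign share in advance. In the data the SD between replicates was 0.52 and 0.53 for shGFP against 0.41 and 0.40 for the hairpins. The simulation therefore understates what shared controls add, and no conclusion is drawn from it. Without shGFP replicate 2 limma called 596 records in 1 direction in both comparisons, and 1948 without shGFP replicate 1, against 102 with all libraries; without 1 of the hairpin libraries it called 2 to 7.

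**Figure D3:**
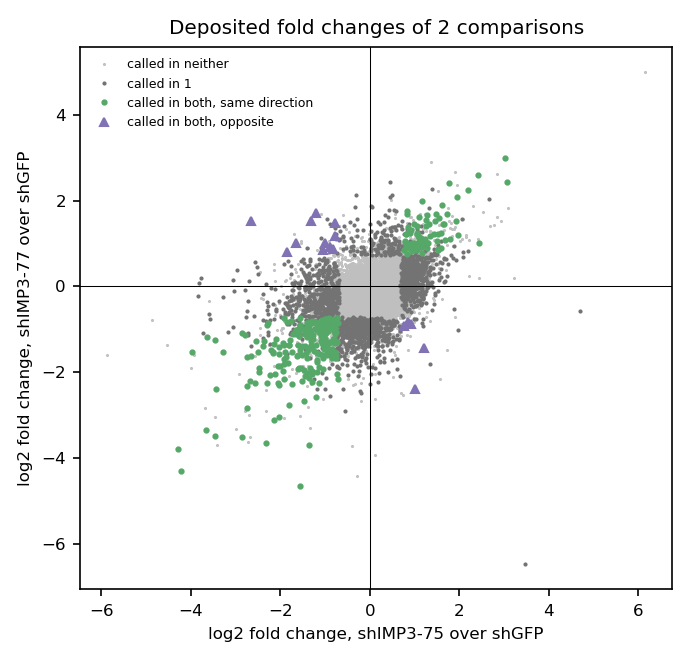
Log2 fold changes from the authors' deposited table with shIMP3-75 (horizontal axis) and shIMP3-77 (vertical axis), 1 point for each of 12792 records with at least 1 FPKM in a group of each table. Of these, 77 were called higher in both and 219 lower in both (larger points), and 16 were called in opposite directions (triangles).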

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

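The tests without a shGFP library, those that count hairpins and those of scaling in each part of the 17 records were chosen only after the result was seen.

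Records called in both comparisons in opposite directions numbered 17, against 48.7 for independent lists and 0.920 in simulated unchanged groups that share controls. In that simulation shared controls push top-ranked records in 1 direction, so a low count was set in advance. No conclusion is drawn from it. In 16 of the 17 records every library of one hairpin lay above both shGFP libraries and every library of the other below. Of all called records, 99.1% with shIMP3-75 and 98.3% with shIMP3-77 had hairpin libraries that did not overlap the shGFP libraries. The 16 therefore follow from the calls and add no further evidence. The difference between the hairpins was not tested. In the authors' deposited table the log2 fold changes with shIMP3-75 and shIMP3-77 were -2.66 and 1.52 for IGFBP3, -1.32 and 1.52 for S100A2, -1.20 and 1.72 for STC1, -1.65 and 1.01 for CXCL1, -0.99 and 1.02 for COL1A2, and 1.21 and -1.43 for CCNG1. With both tables centred on their medians, 70.6% of the 17 were still called in opposite directions, but centring enlarged both folds of 12 of them, so that this decides nothing for the whole group. For these 12, lower with shIMP3-75 and higher with shIMP3-77, scaling is argued against. It would need medians below 0 with shIMP3-75 and above 0 with shIMP3-77, and every pair of a hairpin and a shGFP library lay the other way, by a median log2 ratio of at least 0.0487. For the other 5, centring could not decide on scaling as the cause. All 5 kept their opposite signs after it, at least 2.63 standard errors from 0, but this was fixed in advance. The records were chosen as called, and the medians of 0.112 and -0.115 were smaller in size than every fold of these records. A shift of that size alone could not have turned their signs. Whether the 5 are called does depend on scaling: 0% were still called in both after centring. The standard errors were rebuilt from each deposited fold and p, where no p is below 5e-05. For CCNG1 the deposited test statistics (2.68 and -2.50) would give larger ones. From the authors' deposited table, the log2 fold changes with shIMP3-75 and shIMP3-77 went from 1.21 and -1.43 to 1.10 and -1.31 for CCNG1 (standard errors 0.320 and 0.442), and from 1.00 and -2.39 to 0.892 and -2.27 for PADI3 (0.311 and 0.589). They went from 0.852 and -0.836 to 0.74 and -0.721 for ACOT7 (0.238 and 0.266), from 0.922 and -0.865 to 0.81 and -0.751 for BBS2 (0.248 and 0.259), and from 0.772 and -0.925 to 0.66 and -0.81 for MED30 (0.251 and 0.273) in the authors' deposited table. The calls ended because a shift smaller than the standard error took folds near the threshold below it. After centring 24 records were called in opposite directions, so the count and its members depend on scaling. An off-target effect of one hairpin may account for genes such as IGFBP3, and so may an unequal biological response to the depth of knockdown; with 2 hairpins against the target these cannot be told apart.

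Interferon-stimulated and ATF4-response genes were lower with both hairpins. A high level in shGFP replicate 2 as the whole cause is argued against, since without that library the larger adjusted p of the 2 comparisons was 0.000141 for the interferon-stimulated genes and 0.000633 for the ATF4-response genes (camera of limma, preset correlation), both still lower with the hairpin. The p-values without that library measure spread across genes, so they cannot show whether shGFP replicate 1 itself stood apart. With all libraries and an estimated correlation neither list passed (adjusted p = 0.721 for each). How much of the fall against both controls comes from shGFP replicate 2 cannot be told. With shIMP3-77 the ATF4-response median was -0.35 and -0.40 in the 2 hairpin libraries against shGFP replicate 1, and -0.72 against both controls; for the interferon-stimulated genes it was -0.28 and -0.46, and -0.56. The shGFP hairpin itself may have raised these genes in both of its libraries. With 1 control hairpin this cannot be told apart from a fall that follows the loss of IMP3, and the biological explanation stays untested.

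Cytosolic ribosomal protein genes were higher with shIMP3-75. Transcript length and expression level do not account for the whole rise. The list's median of 0.72 lay at percentile 100 of 10000 random lists matched on both, of which the highest reached 0.43. The matched lists had a median of 0.21, so part of the rise may go with length and expression. Random lists hold unrelated genes, which may vary together less than these do, so the percentile may overstate the contrast. All 76 members had a length. A low level in shGFP replicate 1 as the whole cause is argued against by the list medians. Relative to shGFP replicate 1, the shIMP3-75 libraries lay at 0.86 and 0.89 (log2), and shGFP replicate 2 at 0.28. By these medians both hairpin libraries lay above both shGFP libraries. Without shGFP replicate 1 the adjusted p was 4.48e-10 (camera of limma, preset correlation). That p measures spread across genes, so it cannot show whether shGFP replicate 2 itself stood low. With all libraries and an estimated correlation the list did not pass (adjusted p = 0.695). Reads shared with pseudogenes and a biological response to the knockdown remain open and untested.

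MTRNR2L8, in a record without a usable test (too many reads by the authors' status), was listed at 22719 FPKM with shIMP3-75 and 17742 FPKM with shIMP3-77 and at 0 in shGFP; MALAT1 was listed at 0 in every group, so that a 0 in these records can be a failed estimate.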

How the results depend on the processing

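The limma fits with another pseudocount, filter or centring, limma in place of the authors' test, single-record symbols and camera on the authors' statistic were chosen after seeing the data. With the authors' test, calls for shIMP3-75 and shIMP3-77 numbered 787 and 588 at q 0.01, 847 and 680 with an absolute log2 fold change of at least 1, and 497 and 403 with that minimum on log2(FPKM + 1) ratios. Genes called in both in 1 direction numbered 158 at q 0.01 and 189 with the fold minimum; fewer calls follow from stricter thresholds. Limma called 340 with shIMP3-77 and 102 in both. At pseudocount 0.1 it called 731 and 150, and the cause was not tested. Without 1 library it called 21 to 4640 with shIMP3-75, 14 to 4776 with shIMP3-77 and 2 to 1948 in both. In these fits the lone sample is assumed to vary like the other group. The adjusted p of IGF2BP3 ran from 0.0163 to 0.326 and from 0.000998 to 0.272. With the replicate number as a block limma called 2656 and 63. Deviations of same-numbered libraries correlated at 0.20 and -0.0828, and 2 pairs cannot show whether the numbers pair the samples. The correlation of fold changes was 0.537 with a pseudocount of 1. Of 19 list calls, 11 passed with a preset correlation of 0.05 and 0 with an estimated correlation. The range over the other camera settings with all libraries was 19 to 22. A rotation test, fry of limma, gave unadjusted p = 0.0639 and 0.0717 for the interferon-stimulated list and 0.133 and 0.0727 for the ATF4 list. Its p with shIMP3-75 was 0.0999 for collagens, 0.0514 for mesenchymal and 0.185 for epithelial genes. For ribosomal proteins with shIMP3-77 it was 0.376. The other list calls had a fry p below 0.05. Counts over both directions stayed within 1.5 times of the reported ones at q 0.10, with q recomputed, with at least 1 FPKM, after centring and on symbols with a single record. By direction, higher calls with shIMP3-75 went from 613 to 395 after centring, and genes higher in both from 78 to 124 at q 0.10. IGF2BP3 kept its call in each of these that applied to it. Among named genes, 11 calls were lost and 6 gained after centring, 5 were gained with q recomputed, 82 folds moved by over 1 SD and 160 did not with a pseudocount of 1, and no called gene changed sign in these. Against 1 shGFP library, chosen after seeing the data, the fold moved by over 1.5 times in 16 (without replicate 1) and 20 (without replicate 2) of 176 calls. The log2 ratio of CA11 with shIMP3-77 ran from -1.77 to 0.0349 and changed sign. Tests of the difference between hairpins and a count test were not run. Absolute depth is unknown, so no floor is given for low FPKM.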

Other observations

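Other groups fixed before the data were examined showed single genes that moved with both hairpins. Of 32 genes of glycolysis and hypoxia 4 rose and 2 fell with shIMP3-75 and 2 rose and 1 fell with shIMP3-77, with the glucose transporter SLC2A1 (log2 fold changes 0.81 and 1.00 in the authors' deposited table) and the hexokinase HK2 (0.85 and 0.96) higher in both; the list was not past the threshold (adjusted p = 0.627 and 0.228). Adjusted over the list alone, 4 rose and 4 fell, and 2 rose and 1 fell. Of 24 p53 target genes 3 rose and 6 fell, and 1 rose and 4 fell (adjusted p = 0.266 and 0.764), and adjusted over the list alone 3 rose and 7 fell, and 2 rose and 6 fell. Among them BTG2 rose (1.68 and 1.09), and GDF15 (-1.55 and -4.66) and PHLDA3 (-1.39 and -0.96) fell in both in the authors' deposited table. MUC1, a luminal marker, fell in both (-2.15 and -1.55), as did SCD, the stearoyl-CoA desaturase (-0.92 and -0.97), and DKK1, a Wnt antagonist (-2.16 and -1.53), in the authors' deposited table. ITGA5, the alpha chain of the fibronectin receptor, rose (1.05 and 1.22) and ITGA7 fell (-1.52 and -2.19) in the authors' deposited table.

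Genes with a strong response to one hairpin included PRRG4, at 4.49 ± 0.36 FPKM (SD, n = 2) with shIMP3-75 against 35.4 ± 1.4 (SD, n = 2), and at 48.8 ± 0.16 against 37.4 ± 1.6 (SD, n = 2) in the shIMP3-77 table. ATP2B4, a plasma membrane calcium pump, was at 33.9 ± 0.50 FPKM (SD, n = 2) with shIMP3-77 against 7.68 ± 1.4 (SD, n = 2), and at 10.3 ± 0.20 against 7.26 ± 1.3 (SD, n = 2) in the shIMP3-75 table. TIMP2 was at 39.3 ± 3.7 against 45.4 ± 7.7 FPKM (SD, n = 2) in the shIMP3-75 table. The difference between hairpins was not tested for these genes. Of 21 non-canonical Wnt genes, 1 rose, the receptor ROR1 (log2 fold change 1.83 in the authors' deposited table), and 4 fell with shIMP3-75, among them PTK7 (-1.56), against 1 rise and 1 fall with shIMP3-77 (1 and 6, and 2 and 3, adjusted over the list alone), and the list was not past the threshold in either comparison (adjusted p = 0.132 and 0.276). The lists of cholesterol and fatty acid synthesis (adjusted p = 0.266 and 0.213), replication-dependent histones (0.222 and 0.213), stem cell-associated genes (0.899 and 0.138), Wnt/beta-catenin targets (0.813 and 0.874), basal markers (0.899 and 0.0533) and luminal markers (0.303 and 0.383) were not past it either by camera of limma. Heat shock genes were not past it with shIMP3-75 (adjusted p = 0.274), nor Hippo components, epithelial genes, G2/M genes, RAS/MAPK output or RNA interference genes with shIMP3-77 (adjusted p = 0.0849, 0.213, 0.0849, 0.829 and 0.653). Some of these lists passed by camera of limma when 1 library was left out. Cholesterol and fatty acid synthesis passed, higher, with shIMP3-75 without shGFP replicate 1, but not without shGFP replicate 2. With shIMP3-77 that list passed, lower, without shGFP replicate 2, but not without shGFP replicate 1. The histones passed, lower, in both comparisons without shGFP replicate 2, but in neither without shGFP replicate 1. With shIMP3-77 the basal markers passed, higher, without shGFP replicate 2 or shIMP3-77 replicate 2, but not without shGFP replicate 1. The G2/M genes with shIMP3-77 passed, higher, without shGFP replicate 1 or shIMP3-77 replicate 2, but not without shGFP replicate 2. With the test statistic of the authors' deposited table in camera, the basal markers passed with shIMP3-77 (adjusted p = 0.00986). By camera of limma with an estimated correlation they did not (adjusted p = 0.678).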
